A study of Homo sapiens with 6 samples.

How the data were processed

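RNA was extracted with TRIzol from OVCAR8 cells plated at 300000 per well in medium with 10% serum, and libraries were made with a stranded total RNA kit, per the labels' protocols. The deposited values are raw counts of reads per gene, 1 table per library with unstranded, forward and reverse columns as STAR writes them, per the submitters' processing notes, which name STAR and hg38. The version of STAR and the annotation release are not given in the sources used here. The authors also deposited a merged count table. It holds 28381 lines, and the counts of all 24635 gene IDs it shares with the reverse column, after lines without counts and repeated IDs were left out, equalled that column exactly. The reverse column was used, because it held 17.8 to 19.8 times the gene reads of the forward column, as the kit's chemistry gives. Of 58037 gene IDs, 57433 matched GENCODE release 29 on GRCh38, the same assembly as the authors' build, and names were brought up to date through a table of current symbols.

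Lines for unmapped, multimapping, ambiguous and no-feature reads were kept out of library sizes and tests. Their shares were 6.73% to 17.4% unmapped, 5.31% to 27.0% multimapping, 2.36% to 4.18% ambiguous and 17.5% to 32.0% outside annotated exons of the counted strand. The last share also holds reads within exons on the other strand. Gene reads ran from 11939148 to 22426768 per library. STAR counts leave out reads that map to several places, so genes with near-identical copies are undercounted. At these depths the median standard error of a log2 fold change was 0.16 over all tested genes, and 0.09 over the 5993 genes with an average log2 CPM of 5 or more.

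From these counts, genes were filtered with edgeR's default filter, scaled by TMM and compared by edgeR 4.0.16's quasi-likelihood F test (two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with limma 3.58.1. All 6 libraries entered 1 fit with treatment as the only term. The 29 gene lists were tested with camera at a preset correlation of 0.01 where 3 or more members were tested, and again with an estimated correlation and with fry. The genes named are, in each direction, the 12 largest changes past the threshold or, as no gene passed, the 6 with the smallest p among genes with an average log2 CPM of at least 1 and groups that do not overlap. The 2 members with the smallest p of each list described by its members, RLN2 and RXFP1 were also named, and pseudogenes, small RNAs, unnamed clones and most long noncoding RNAs only where no named gene with a known product was left. Lists, rule, tests and most alternatives were fixed before the data were examined. The histone genes H3C2 and H3C3 were at first matched to a wrong gene ID through shared synonyms, and this was corrected after results had been seen. RNY4, HSPB1, MT-RNR1, MT-RNR2 and the other genes named only for an alternative setting, and classes of gene named in the closing section, were chosen after their values were seen.

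The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, robust quasi-likelihood fits, other scalings, other filters, unstranded counts, the merged table, removal of small RNA, mitochondrial and histone genes, an adjusted p under 0.10, leaving out each library, and the replicate number as a block. Added after seeing the data were offsets that remove each library's smooth trend (natural splines with 4 knots) on transcript GC content and log length, 1 surrogate variable from sva 3.50.0, leaving out both libraries numbered 2, and list tests under 2 further scalings. GC content and length were the mean over a gene's GENCODE 29 transcripts and were known for 99.6% of tested genes. Tests of single library measures were exact permutation tests over the 20 assignments. Counts drawn from the fitted means and dispersions with 66 genes changed at each of 1.5-fold, 2-fold and 4-fold, and real counts thinned in the same way, were used to check the test. It recovered 90.9% of the 4-fold changes in drawn counts, with 10 false among 130 calls, and 19.7%, 57.6% and 81.8% of the 1.5-fold, 2-fold and 4-fold changes in thinned counts, with 1 false among 106 calls. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.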

Results

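The transcriptome of OVCAR8, an established human ovarian carcinoma cell line, was measured with and without relaxin-2 (RLN2), a secreted peptide hormone of the insulin superfamily. Cells were kept without serum for 16 hours and then left untreated or given 50 ng/mL of the recombinant human hormone for 8 hours. Total RNA was sequenced from 3 untreated libraries, numbered 2 to 4 in the labels, and 3 relaxin-2 libraries, numbered 1 to 3. The untreated libraries held 22166723, 22426768 and 17175308 reads assigned to genes, and the relaxin-2 libraries 17994116, 11939148 and 21926212. The labels describe triplicates without saying whether these were separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise, so each library counted as 1 sample. The chi-square per degree of freedom over genes was 2.47 for the closest pair, untreated replicate 4 and relaxin-2 replicate 1, and 5.64 for the closest pair within a group, relaxin-2 replicates 1 and 3.

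The transcripts of the hormone and of its receptors were at or near 0 in both groups. RLN2 (chromosome 9, 5299868 to 5304969, GRCh38) and its near-identical neighbour RLN1 (chromosome 9, 5334969 to 5339873) had 0 reads in all 6 libraries, which allows up to 0.0264 on the counts-per-million (CPM) scale by the floor of 3 counts over the 113628275 gene reads. RXFP1, the main relaxin-2 receptor (chromosome 4, 158315311 to 158653372), had 1 read, in untreated replicate 2, giving an exact two-sided 95% upper limit of 0.0490 CPM over all libraries. RXFP2, RXFP3, RLN3 and INSL6 also had 0 reads, RXFP4, INSL3 and INSL4 had 1 read each, and INSL5 had 2. Reads that fit both RLN1 and RLN2 equally well are not in the counts, so for this pair the values are uncertain. These limits cover counting error only, and no difference between the groups was detectable at this depth.

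The main comparison asked which genes differ in OVCAR8 cells after 8 hours of relaxin-2. No gene passed the threshold among the 16740 tested (edgeR quasi-likelihood test, smallest Benjamini-Hochberg adjusted p = 0.408), so the genes below were picked by a fixed rule and none is called changed. The rule takes the smallest p in each direction but passes over small RNAs, pseudogenes, most long noncoding RNAs, genes of low abundance and genes whose groups overlap. Among the 6 picked as higher after relaxin-2, the largest fitted differences were in FOXL2, a forkhead transcription factor of the ovary, with a log2 fold change of 1.16 ± 0.27 (SE), and in ZSWIM9, a zinc finger SWIM-type gene (chromosome 19, 48170692 to 48197620), with 1.08 ± 0.20. ZSWIM9 went from 1.54 ± 0.30 to 3.29 ± 0.21 CPM (mean ± SD, n = 3 libraries per group), and FOXL2 from 1.23 ± 0.31 to 2.77 ± 0.76 CPM. TMEM79 (0.83 ± 0.18) and ZBTB12 (0.74 ± 0.16) also had few reads, while PRCC (0.46 ± 0.11) and TOB2, an antiproliferative gene of the BTG/TOB family (0.43 ± 0.10), were more abundant, TOB2 with 65.2 ± 7.66 CPM untreated and 88.1 ± 6.77 CPM treated.

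In the other direction small RNAs, among them RNU4-1, RNU4-2 and RNY4, had smaller p than the 6 genes picked by the rule. Of these 6, RANBP17, a nuclear transport receptor (chromosome 5, 170861870 to 171300015), had 70.9 ± 4.12 CPM untreated and 54.9 ± 2.03 CPM after relaxin-2, a log2 fold change of -0.37 ± 0.08. CPLANE1 and TBC1D32, which act in primary cilia, had log2 fold changes of -0.30 ± 0.07 and -0.40 ± 0.09, and PTBP2, a splicing regulator, -0.35 ± 0.08. The zinc finger genes ZNF586 and ZNF781 had -0.56 ± 0.13 and -0.50 ± 0.11. In each of these 12 genes all relaxin-2 libraries lay on one side of all untreated libraries, as the rule requires. The same held in 3574 of the tested genes, or 21.4%. Chance gives 10% on average over groupings, but genes here move together, so a single grouping can lie far from that without a treatment effect. With the GC content and length offsets described with the processing, 9 of the 12 moved toward 0 by over 1.5 times, among them ZSWIM9 to 0.54, FOXL2 to 0.52, ZBTB12 to 0.15, TOB2 to 0.01 and RANBP17 to -0.21. With 1 surrogate variable as a covariate FOXL2 was 0.71 and TOB2 0.24. With no filter on low counts ZSWIM9 (adjusted p = 0.0410) and FOXL2 (0.0422) passed edgeR's test.

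**Figure D1:**
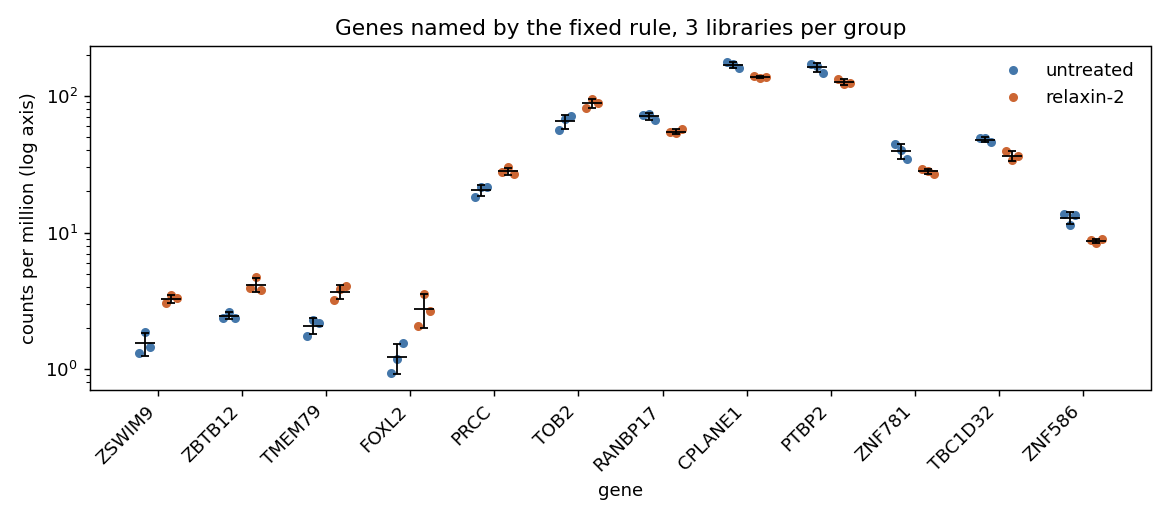
CPM of the 12 genes picked by the rule, 6 per direction, on a log axis, in the 3 untreated and 3 relaxin-2 libraries. Points are libraries, bars the mean ± SD; the rule takes only genes whose groups do not overlap, and the adjusted p of each gene was 0.408 in edgeR's quasi-likelihood test.

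An unadjusted p under 0.05 was reached by 1811 genes, 1055 higher and 756 lower after relaxin-2. Chance gives 837 on average over groupings, and here too a single grouping can lie far from that. DESeq2 and limma-voom also called 0 genes, with 1677 and 2058 at an unadjusted p under 0.05. Without a filter on low counts, edgeR called 120 genes (115 higher and 5 lower), and without untreated replicate 2 it called 3, all lower: the spliceosomal RNAs RNU4-1 and RNU4-2 and the small RNA RNY4. On counts drawn with known changes, the same test recovered 59.1% of genes changed 2-fold and 31.8% of those changed 1.5-fold, and 100% and 70.4% of those at an average log2 CPM of 5 or more. On real counts thinned to the same changes it recovered 57.6% and 19.7%, and 96.4% and 47.8% of the abundant ones. All these changes were present at once, which loosens the Benjamini-Hochberg cut. If few genes changed, a smaller share would be recovered, so these shares do not rule out 2-fold changes in abundant genes.

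Pathways that the relaxin receptor is known to reach were examined as gene lists fixed before the data were examined. In the list of cAMP/CREB targets 10 members were higher and 11 lower. FOSB (0.50 ± 0.23) and CRTC1 (0.68 ± 0.32), a CREB coactivator rather than a target, had the smallest p. NF-kB targets were split evenly, 14 higher and 14 lower, among them the chemokine CXCL1 (-0.68 ± 0.22) and the cytokine LIF (0.51 ± 0.16). ERK feedback targets had 13 higher and 9 lower members, with FOSL1, an AP-1 subunit, at 0.45 ± 0.18 and the ephrin receptor EPHA4 at -0.38 ± 0.15. None of these lists was shifted against the other genes (edgeR fit with camera, adjusted p = 0.790, 0.631 and 0.535), and 0 of their members passed, either over all genes tested or adjusted over the list alone. Without untreated replicate 2 the log2 fold change of CRTC1 was 0.35 and that of FOSL1 0.28. With the offsets FOSB was 0.10, CRTC1 0.04, LIF 0.12 and FOSL1 0.01, and with 1 surrogate variable they were 0.25, 0.04, 0.26 and 0.09. With the offsets the ERK list's median went from 0.04 to -0.08, with a camera adjusted p of 0.00815. Over the alternatives the list's adjusted p ran from 0.00815 to 0.873 (0.848 with an estimated correlation, 0.535 with fry).

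Matrix genes, a known class of relaxin targets, also held no member past the test in the main fit, with 0 over all genes and 0 adjusted over the list alone. COL1A1, the main fibrillar collagen chain, had 62.2 ± 23.6 CPM untreated and 112 ± 20.3 CPM after relaxin-2 (log2 fold change 0.84 ± 0.27), and LOXL2, a collagen cross-linking enzyme, had 0.54 ± 0.22. LOXL2 was 0.33 without untreated replicate 2 and 0.11 with the offsets, and COL1A1 was 0.42 with the offsets. With 1 surrogate variable COL1A1 was 0.29 and LOXL2 0.09. With no filter on low counts COL1A1 (adjusted p = 0.0168) and COL6A2 (0.0441) passed edgeR's test, both higher. Of the 16 tested members of the collagen and matrix list 9 were higher and 7 lower (camera adjusted p = 0.0603). The direction fixed in advance was lower for this list and higher for the proteases. Every pass of the collagen list given below was upward, against the direction fixed for it. Of the 11 matrix proteases and inhibitors 9 were higher and 2 lower (camera adjusted p = 0.0665). They included the inhibitor TIMP2 (0.24 ± 0.08), and the collagenase MMP1 had -0.35 ± 0.10, and with the offsets these were 0.14 and -0.22. The protease list's median of 0.23 was 0.10 without untreated replicate 2 and 0.02 with the GC content and length offsets (adjusted p = 0.490), and over all alternatives its adjusted p ran from 0.0447 to 0.860 (0.784 with an estimated correlation, 0.388 with fry). The collagen list passed without untreated replicate 2 (adjusted p = 0.0475), without untreated replicate 4 (0.0286), without relaxin-2 replicate 1 (0.0344) and without relaxin-2 replicate 2 (0.0452). It also passed with no filter (0.0101), with unstranded counts (0.0202), with the offsets (0.00311) and without both libraries numbered 2 (0.0453), and over all alternatives its adjusted p ran from 0.00134 to 0.860. With an estimated correlation its adjusted p was 0.784 and with fry 0.388. Its median of 0.10 was 0.05 without untreated replicate 2 and -0.01 with 1 surrogate variable.

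Growth, stress and identity lists gave no shift in the same camera test. In the proliferation list 13 members were higher and 17 lower (adjusted p = 0.994), with TYMS, thymidylate synthase, at 0.30 ± 0.10 and PLK1, a mitotic kinase, at 0.36 ± 0.15. Hypoxia and angiogenesis genes had 9 higher and 9 lower (adjusted p = 0.899), including VEGFA at 0.30 ± 0.11 and PDK1 at -0.34 ± 0.10. VEGFA turned to -0.01 with the offsets. Epithelial and ovarian cancer markers had 8 higher and 2 lower (adjusted p = 0.247), with KRT8, an epithelial keratin, at 0.47 ± 0.22 and PAX8, a Müllerian lineage factor, at 0.30 ± 0.17. PAX8 turned to -0.05 with the offsets. Without untreated replicate 2 the values were 0.20 for PLK1, 0.19 for VEGFA, 0.23 for KRT8 and 0.12 for PAX8, and without relaxin-2 replicate 2 TYMS was 0.18. With the offsets PLK1 was 0.08 and KRT8 0.18, and with 1 surrogate variable VEGFA was 0.10, PLK1 0.08, KRT8 0.0036 and PAX8 -0.04. The adjusted p was 0.535 for Wnt/beta-catenin, STAT3, TGF-beta, p53, unfolded protein and mesenchymal lists, 0.608 for YAP/TEAD, 0.777 for interferon-stimulated genes, 0.899 for stemness and drug resistance, 0.902 for FOXO and 0.305 for cholesterol synthesis targets. The cholesterol list passed without untreated replicate 2 (0.0475), without both libraries numbered 2 (0.0380) and with the offsets (0.0439), with a range over the alternatives from 0.0380 to 0.784 (0.784 with an estimated correlation, 0.311 with fry). For the cAMP/CREB, proliferation, interferon, FOXO and stemness lists the median log2 fold change and the camera direction were negative and the mean was positive. In the main fit 0 members of the lists named so far passed over all genes and 0 adjusted over the list alone. With no filter on low counts MVD of the cholesterol list passed edgeR's test beside COL1A1 and COL6A2.

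The lists that did pass were 2 of the 27 tested, both fixed as signs of RNA selection and quality. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, passed on the higher side after relaxin-2 (camera adjusted p = 0.000147). Of 19 members 18 were higher, with a list median log2 fold change of 0.40, H1-4 at 0.63 ± 0.27 and H2BC9 at 0.45 ± 0.21. The groups overlapped in every tested member. The list's median deviation from a gene's mean over all libraries was -0.81 in untreated replicate 2. It was 0.21 in untreated replicate 4, above the 0.039 of relaxin-2 replicate 1. Mitochondrially encoded genes also passed on the higher side, 13 of 15 members with a list median of 0.28 (camera adjusted p = 0.00416), MT-ND1 at 0.69 ± 0.18 and MT-ND2 at 0.29 ± 0.12. Their median deviation was 0.055 in untreated replicate 2, above the -0.046 of relaxin-2 replicate 3. Neither call held with an estimated correlation (adjusted p = 0.784 for both lists). The estimate was 0.94 for histones and 0.43 for mitochondrial genes, far above the preset value. Members of each list moved together, so the counts of higher members are not independent observations. In the main fit 0 members of these lists passed over all genes or adjusted over the list alone. With no filter on low counts MT-ND1 (adjusted p = 0.0150), MT-RNR2 (0.0228), MT-RNR1 (0.0303) and H1-4 (0.0447) passed edgeR's test. The histone median was 0.15 without untreated replicate 2, 0.64 without untreated replicate 4, 0.10 without both libraries numbered 2 and 0.24 with the GC content and length offsets, and with 1 surrogate variable as a covariate the list passed in the opposite direction (median -0.10, adjusted p = 0.000351). Without untreated replicate 2 H1-4 was 0.36 and H2BC9 0.24, and without untreated replicate 4 H2BC9 was 0.69. H1-4 was 0.24 with the offsets, and with 1 surrogate variable H1-4 was 0.07, H2BC9 0.03 and MT-ND2 0.44. The mitochondrial median was 0.14 without untreated replicate 3, 0.42 with the offsets and 0.44 with 1 surrogate variable, and the mitochondrial call was lost without untreated replicate 3 (adjusted p = 0.157), untreated replicate 4 (0.0751) or relaxin-2 replicate 1 (0.0773). Over all alternatives the adjusted p ran from 7.66e-15 to 0.784 for histones and from 3.32e-16 to 0.784 for mitochondrial genes.

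Ribosomal protein genes, with 22 members higher and 8 lower, did not pass (camera adjusted p = 0.0647), RPLP1 at 0.77 ± 0.29 and RPL3 at 0.30 ± 0.12, and without untreated replicate 2 these were 0.48 and 0.19. With 1 surrogate variable RPLP1 was 0.21 and RPL3 0.08, and with the offsets RPL3 was 0.08. With no filter on low counts RPLP1 passed edgeR's test (adjusted p = 0.0246). The list's median of 0.12 was 0.03 without untreated replicate 2 and turned to -0.02 with 1 surrogate variable. It was 0.20 without untreated replicate 4, 0.06 with the offsets and 0.23 with the replicate block. The list passed with no filter (0.00740), with unstranded counts (0.00644), without untreated replicate 4 (0.0165), without relaxin-2 replicate 2 (0.0377) and with the offsets (0.0402), and over all alternatives its adjusted p ran from 0.00121 to 0.879 (0.784 with an estimated correlation, 0.388 with fry). Small structural RNAs had 4 tested members, 1 higher and 3 lower (camera adjusted p = 0.0603). Summed over these members, abundance went the other way, from 5500 CPM in untreated to 8542 CPM in relaxin-2 libraries. RN7SK, RN7SL1 and RN7SL2 together held 0.263%, 0.676% and 0.691% of gene reads in untreated replicates 2, 3 and 4. In relaxin-2 replicates 1, 2 and 3 their joint share was 0.685%, 0.892% and 0.926%. The list passed, lower, without untreated replicate 2 (0.00231), without relaxin-2 replicate 2 (0.0103) and without both libraries numbered 2 (2.48e-05). It also passed with the offsets (0.0144), with no filter (0.0202) and with 1 surrogate variable (5.47e-07). With the merged table it passed at 0.05 as rounded, just under the threshold. Over all alternatives the list's adjusted p ran from 5.47e-07 to 0.784 (0.784 with an estimated correlation, 0.311 with fry). The U4 spliceosomal RNAs RNU4-2 (85.7 ± 9.24 CPM untreated, 57.1 ± 6.19 CPM treated, log2 fold change -0.59 ± 0.11) and RNU4-1 (-0.64 ± 0.12) are near-identical copies, so their split of reads is uncertain. With the offsets RNU4-2 was -0.37. In the main fit RNU4-1 and RNU4-2 were the 2 members of any list that passed when adjusted over the list alone (smallest edgeR adjusted p = 0.00146). Over all genes 0 members passed in that fit. The nuclear long noncoding RNAs had 1 higher and 6 lower members (camera adjusted p = 0.325). Summed over these members, abundance again went the other way, from 10425 CPM in untreated to 11522 CPM in relaxin-2 libraries.

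**Figure D2:**
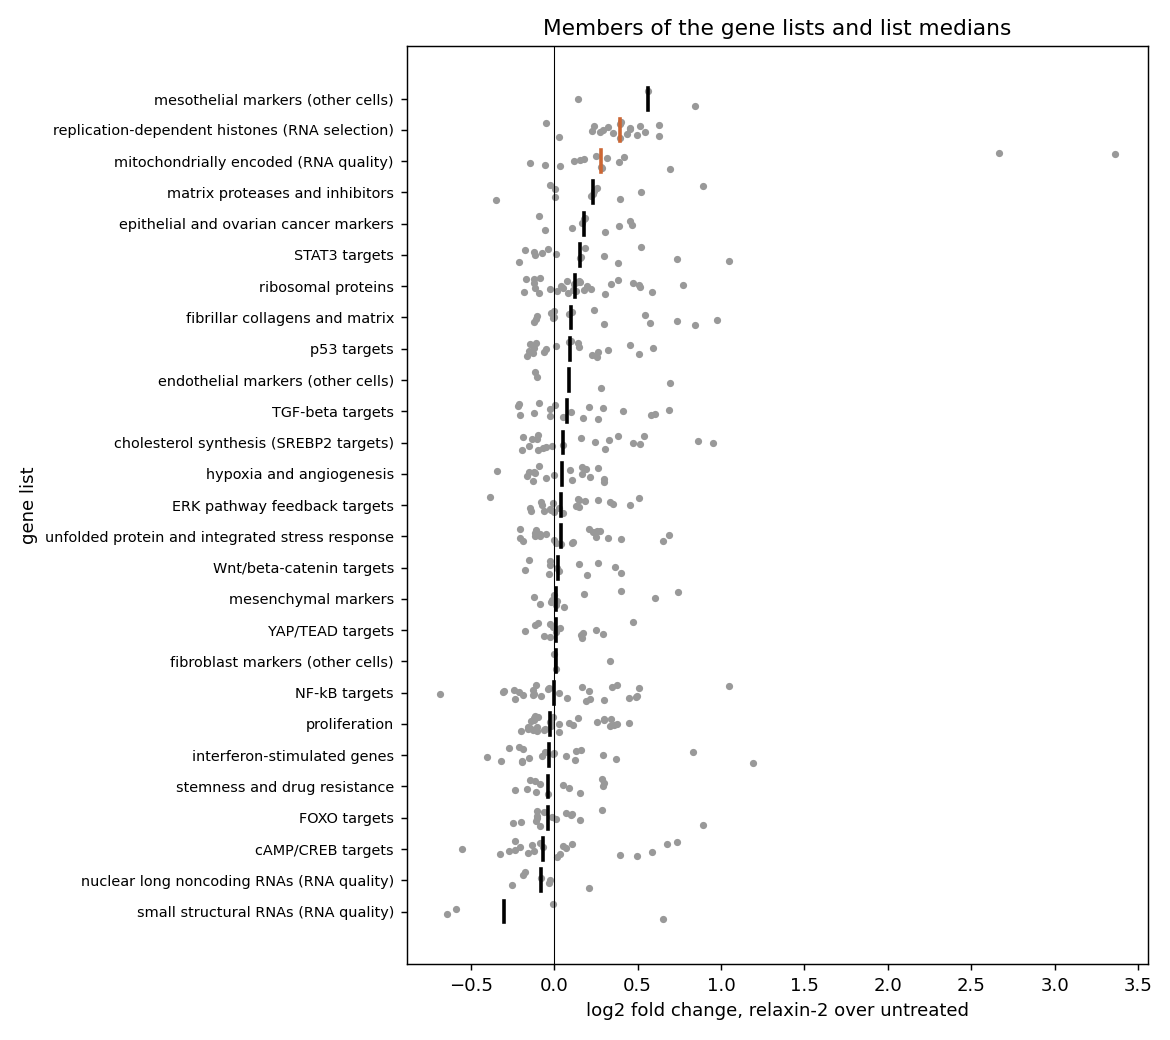
Log2 fold change of relaxin-2 over untreated for each tested member (points) of the 27 gene lists, with list medians as vertical bars, orange where the camera adjusted p was under 0.05. The histone and mitochondrial medians lie at 0.40 and 0.28, and the points near 3 are the mitochondrial rRNAs; with 1 surrogate variable the histone median is -0.10 and the ribosomal protein median -0.02.

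Markers chosen for other cell types were low in total. The 3 tested fibroblast markers summed to 16.2 CPM in untreated and 19.7 CPM in relaxin-2 libraries (adjusted p = 0.777), the 4 endothelial markers to 7.08 and 7.13 CPM (0.790), and the 3 mesothelial markers to 24.0 and 41.7 CPM (0.129), all in camera. The mesothelial list passed, higher, without relaxin-2 replicate 2 (0.0377) and without both libraries numbered 2 (0.0380). Over all alternatives its adjusted p ran from 0.0377 to 0.784 (0.784 with an estimated correlation, 0.388 with fry). MSLN held most of its total, at 20.9 ± 10.9 CPM untreated and 37.5 ± 7.75 CPM after relaxin-2. The groups overlapped for MSLN, and untreated replicate 2 had 8.55 CPM, below the 25.4 and 28.9 CPM of untreated replicates 3 and 4. Whether MSLN marks other cells here was not tested. The 12 leukocyte markers had 110 reads over all libraries and none could be tested.

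Libraries stood apart along the GC content of transcripts. The first principal component held 63.3% of the variance, with untreated replicates 2, 3 and 4 at -62.0, -4.30 and 6.76. Relaxin-2 replicates 1, 2 and 3 lay at 3.78, 33.7 and 22.1, so the groups overlapped along it. Across genes, which are not independent replicates, the log2 fold change of relaxin-2 over untreated was higher at higher GC content (Spearman's rho = 0.73, 16673 genes). Among 10 bins of genes ordered by GC content, the richest had a median log2 fold change of 0.56 and the poorest -0.18. Among pairs of libraries across the groups, only untreated replicate 4 and relaxin-2 replicate 1 ran the other way (rho = -0.10). Relaxin-2 replicate 2 also had 4.40% of its gene reads on the mitochondrial rRNAs MT-RNR1 and MT-RNR2, where the other libraries had 0.0408% to 0.374%. Reads outside annotated exons of the counted strand numbered 0.570 ± 0.0469 per gene read in untreated and 0.463 ± 0.0132 in relaxin-2 libraries (mean ± SD, n = 3, exact two-sided permutation p = 0.10, the smallest that 3 against 3 can give, adjusted p = 0.45 over 9 read measures).

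**Figure D3:**
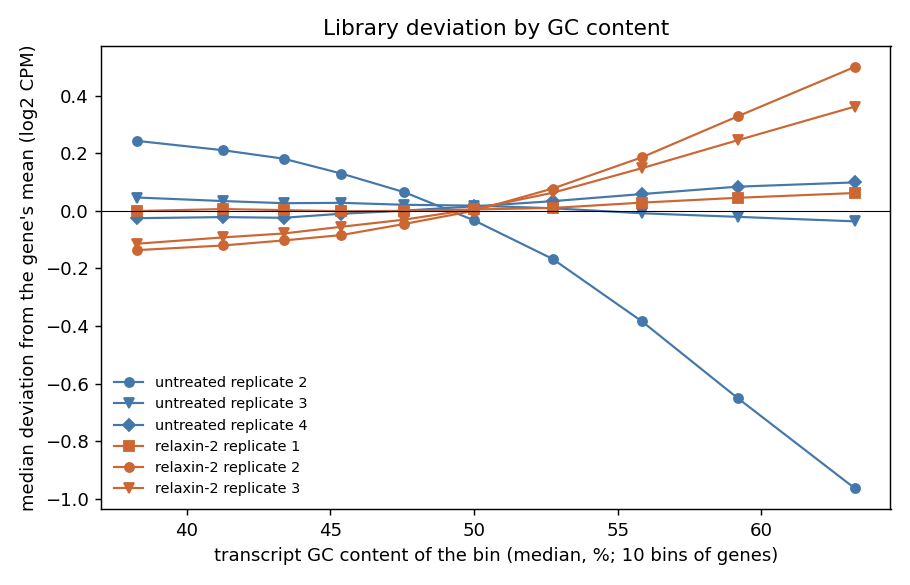
Median deviation of each library from a gene's mean over the 6 libraries, in log2 CPM, for 10 bins of the tested genes ordered by transcript GC content in percent. Blue lines are untreated and orange lines relaxin-2 libraries; untreated replicate 2 falls to -0.96 in the richest bin and relaxin-2 replicate 2 reaches 0.50.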

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

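The tests of the mitochondrial rRNA pattern were chosen after the result was seen. Of all reads in a library, the share that mapped to several places was 27.0% in relaxin-2 replicate 2 and 6.19% in relaxin-2 replicate 3, above the highest untreated library at 5.63%. Unmapped reads made up 17.4% of relaxin-2 replicate 1 and 15.0% of relaxin-2 replicate 2, above every untreated library. In relaxin-2 replicate 3 they made up 6.73%, below every other library. Ambiguous reads made up 4.18% of relaxin-2 replicate 3, above the highest untreated library at 3.50%. The flag looked only for relaxin-2 libraries above the highest untreated library, not for those below. Between the groups, the exact two-sided permutation p was 0.3 for multimapping, 0.5 for unmapped and 0.7 for ambiguous shares.

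In relaxin-2 replicate 2, MT-RNR1 and MT-RNR2 were 5.37 and 4.20 log2 units above the mean of the other 5 libraries, computed on log2(CPM + 1). More mitochondrial RNA in that library is argued against by the 13 mitochondrial mRNAs, whose median rise was 0.14. A rise of 4.20 or more in both rRNAs beside that median is what less complete removal of rRNA in that library may give, and the multimapping share of 27.0% goes with it. Whether relaxin-2 treatment had a part in this was not tested, as relaxin-2 replicates 1 and 3 did not show it.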

How the results depend on the processing

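The GC content and length offsets, the surrogate variable, the fit without both libraries numbered 2 and the list tests under upper-quartile factors and library totals were chosen after seeing the data. The count of 0 genes held with DESeq2, limma-voom, robust fits, every other scaling, the stricter filter, unstranded counts, the merged table, removal of small RNA, mitochondrial and histone genes, an adjusted p under 0.10 and the GC content and length offsets. With no filter there were 120 genes (115 higher, 5 lower) among 32407 tested. Leaving out 1 library gave 0 to 3 genes, 0 higher and 0 to 3 lower, the 3 coming without untreated replicate 2. With 1 surrogate variable 7 genes passed, 7 lower, among them NEAT1, RNU4-1 and RNU4-2. With both libraries numbered 2 left out 3 passed, HSPB1 higher (1) and RNU4-1 and RNU4-2 lower (2). The cause of these differences was not tested. The count of shifted lists was 2 with other scalings and 3 with the merged table and with 1 surrogate variable, where the histone list passed in the opposite direction (adjusted p = 0.000351). It was 5 with no filter, 4 with unstranded counts, 7 with the GC content and length offsets, 6 with both libraries numbered 2 left out and 1 to 6 on leaving out 1 library (1 without untreated replicate 3, 5 without untreated replicate 2, 6 without relaxin-2 replicate 2). Mesothelial markers were among the 6 in both settings with 6. With an estimated correlation and with fry it was 0. With the GC content and length offsets the values of the ERK list (median), VEGFA and PAX8 turned to -0.082, -0.014 and -0.051, and with 1 surrogate variable those of the ERK list, ribosomal proteins, histones, collagens and PAX8 to -0.034, -0.021, -0.096, -0.0076 and -0.042. The other 34 of the 36 genes named from the rule kept their direction in all 22 alternatives that tested them. Of the 36, 24 moved by over 1.5 times with the offsets, 17 with 1 surrogate variable, 15 without both libraries numbered 2 and 11 without untreated replicate 2. Depth and spread limit the size of change that can be called: the test recovered 31.8% of 1.5-fold changes in drawn counts and 19.7% in thinned real counts. Those checks held many changed genes at once, and with few changed genes the share would be smaller.

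The groups share only the numbers 2 and 3, and no label says that they pair cultures. Deviations from the group means correlated at -0.33 for the libraries numbered 2 and 0.12 for those numbered 3. With the replicate block 1 gene passed, MT-RNR1, higher (1), and 5 lists were shifted: mitochondrial, histone (median 0.777), collagen (0.213), ribosomal and protease. The block moved 11 of the 36 genes by over 1.5 times, all away from 0. In that fit, libraries whose number occurs in only 1 group add nothing to the treatment estimate, which rests on those numbered 2 and 3. The block also gave the lowest adjusted p in the ranges printed for the histone, collagen, ribosomal and protease lists.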

Other observations

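The tests below were chosen after the results were seen. For the total of olfactory receptor reads and for sense intronic and zinc finger genes with GC content and length offsets, bounds were set before the test values. The offsets and the classes themselves were chosen after the data were seen. As whole classes, snRNA, snoRNA and scaRNA genes and transcripts from introns lay on the lower side after relaxin-2. The shift was not specific to them. Other noncoding classes also lay lower, among them miRNA genes (median -0.22, 66.7% negative), sense overlapping genes (68.7%), processed transcripts (67.5%) and lincRNAs (60.9%). Antisense genes had a median of -0.017, and protein-coding genes one of 0.0041 (49.5% negative). Of 58 tested spliceosomal-type snRNA genes, RNU4-1, RNU4-2 and RNU1-1 of the fixed lists among them, 48 had a negative log2 fold change, with a median of -0.30, as did 95 of 126 snoRNA and scaRNA genes (median -0.22) and 241 of 324 sense intronic genes (median -0.20), where 52.2% of all tested genes were negative. With the GC content and length offsets the snRNA median was -0.091 (63.8% negative) and the snoRNA and scaRNA median -0.020 (54.0% negative). In the main fit no gene of these classes passed the test over all genes. With 1 surrogate variable SNORA73B (edgeR adjusted p = 0.0019), SNORD3A (0.0153), SCARNA13 (0.0271), RNU4-1 and RNU4-2 passed, all lower. With no filter on low counts SNORA53 (0.0205), RNU4-1 and RNU4-2 passed, also lower. The Y RNA gene RNY4 had the smallest p of all tested genes (edgeR, adjusted p = 0.408), at 1.96 ± 0.45 CPM untreated and 0.57 ± 0.06 CPM after relaxin-2 (mean ± SD, n = 3). Zinc finger (ZNF) genes, a family of transcription factors, had 351 of 473 members on the lower side, with a median of -0.13.

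For the nuclear and intronic RNA, genomic DNA in the untreated libraries would also give reads outside exons. Olfactory receptor genes held 0.671 of the reads that DNA spread evenly over the genome would need, but this bound, set in advance, was wrong: the relaxin-2 libraries, whose mean share of reads outside exons is the level that excess is counted from, held 18.2 ± 1.18 CPM of olfactory receptor reads beside 21.2 ± 1.27 in untreated ones. Counted above the relaxin-2 level, the share was 0.0952, and 0.178 for the widest pair of libraries, which argues against DNA as the whole source. A lower yield of short RNA as the whole source is argued against by sense intronic genes with transcripts over 500 nt, whose median was -0.21, though it was -0.084 with the GC content and length offsets. The GC content and length trend stays open, as offsets moved the sense intronic median from -0.20 to -0.055, and an effect of relaxin-2 on nuclear RNA stays open as untested.

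For the order of fold changes by GC content (rho = 0.73 between the groups), a GC bias of single libraries may be the source, since 2 untreated libraries differed by as much (largest rho within a group 0.737). Untreated replicate 2 is not the whole source, as rho was 0.53 without it. Zinc finger genes have a median GC content of 46.8%, and their median log2 fold change was -0.081 with the offsets, with 347 of 473 members still on the lower side, so whether the GC trend gives all of their shift cannot be told apart from a separate one. An effect of relaxin-2 on GC-rich genes stays open as untested.

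The real split of the 6 libraries into 3 and 3 called 0 genes, so that all 10 splits gave as many was fixed by that count and shows nothing; the highest of the other splits was 0. The real split gave 2 shifted lists, 7 of the 10 splits gave at least as many, and the highest of the others gave 3. With 10 splits a share under 0.05 cannot be reached. At an unadjusted p under 0.05 the real split gave 1811 genes, and the split that sets untreated replicates 2 and 3 and relaxin-2 replicate 1 against the rest gave 2404. The other 8 splits gave 116 to 547.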
